A study of Mus musculus with 8 samples.

How the data were processed

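RNA was measured in 8 tumours, 4 from mice on a high-fat diet, which the labels call obese, and 4 from mice on a regular diet, called lean. The tumours had been snap-frozen in liquid nitrogen, total RNA was extracted with a column kit and libraries were made with a stranded TruSeq kit, per the labels' protocols. The deposited file holds counts, that is, the number of sequencing reads assigned to each Ensembl mouse gene, with 1 column per tumour and no normalization. CASAVA 1.8, bcl2fastq 2.18.0.12, cutadapt 1.12, STAR 2.5.2b, HTSeq and the genome build mm10 are named in the submitters' processing notes. The gene annotation, the strand setting, the read filters and the version of HTSeq are not stated there. The values were whole numbers, which was checked on every cell, and genes at 0 were kept.

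The file lists 50143 gene IDs, of which 30886 had a count of 0 in every library. Symbols and coordinates came from GENCODE M21 (GRCm38, the assembly of mm10), counted from 1. There, 49326 IDs had a symbol and 817 did not. The file's 37 mitochondrially encoded genes had a total count of 0, so their RNA cannot be described from these counts. Total counts ran from 25.7 to 66.7 M counts per library, and 3 counts, the upper limit that a count of 0 allows, correspond to 0.0450 to 0.117 CPM (counts per 1 M counts). That limit covers counting error alone. No pair of libraries was a duplicate of another.

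Groups came from the labels, and the replicate numbers only name tumours. The labels give no batch, date or pairing. The single comparison was obese against lean. Genes were kept by edgeR's filterByExpr on the group (minimum count 10, minimum total 15), which left 14887 genes. They were scaled by TMM factors and tested with edgeR's quasi-likelihood F test (robust, two-sided), adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05. Log2 fold changes are obese minus lean, each with a standard error (SE) taken as the fold change over the square root of F. CPM values are normalised with the TMM factors and given as mean ± SD over 4 tumours per group, obese first.

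A set of 49 gene lists covered other cell types, epithelial states and pathways. Lists with at least 5 tested genes were tested with limma's camera on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the 45 lists so tested. Camera with the correlation estimated per list, which sets each list against other genes, and fry, which tests whether a list's own genes move one way on balance, were run beside it. The mean log2 CPM of each list was computed per tumour and compared by an exact permutation test over the 70 assignments of tumours to groups, two-sided, with Benjamini-Hochberg adjustment. The smallest exact p is 0.0286. Principal components used the 1000 most variable tested genes. The rule for named genes took the 12 largest rises and the 12 largest falls among genes with an adjusted p under 0.05, no overlap between the groups, a mean log2 CPM of at least 0 and a symbol that is no predicted model, clone name or antigen receptor segment. It also took up to 4 members with the smallest p from each list, or the 2 most abundant where no member passed, and the 5 genes with the highest mean count. The text names part of the list members so chosen and says where another gene was chosen after its values were seen. Some genes that the rule chose are not reported here. The test, the lists, the rule and the other settings were fixed before the data were examined.

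The other settings, fixed with the test, were other scaling factors (DESeq2's size factors, upper quartile, library size only), other filters (none, or 1 CPM in 4 tumours), limma-voom without and with sample quality weights, the DESeq2 Wald test, 1 surrogate variable from sva, and leaving out each tumour in turn. Offsets for GC content and exon length, fitted per library by loess for the 14759 tested genes with both values (99.1%), and the estimated correlation without obese replicate 3 were added after the data were seen. No column or gene of the file was left out of the filter step. The versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0.

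The steps were tested on simulated data for obese against lean, with counts drawn for 14723 genes that passed the filter. There edgeR recovered 11.6% of 95 genes changed 2-fold and 63.5% of 96 genes changed 4-fold. It called 2 unchanged genes and gave 0 recovered genes the wrong sign. Camera called 2 of 2 changed lists and 0 of 40 unchanged lists, with the preset and with the estimated correlation. The simulated genes were drawn independently of each other. The simulation therefore does not show how often camera calls unchanged lists whose genes vary together.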

Results

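Messenger RNA levels were measured by RNA sequencing in 8 tumours grown from Py230, a mouse breast adenocarcinoma cell line, in the mammary gland 4 of female C57BL/6 mice. The mice were ovariectomized at an age of 6 weeks and put on their diets 2 weeks later, 6 weeks before the tumour cells were injected. The high-fat diet held 60% of calories as fat (5.1 kcal/g) and the regular diet 10% (3.6 kcal/g), and mice on the former became 35% heavier on average. Tumours were taken on day 56, 4 from obese and 4 from lean mice. The total count was 25.7, 66.7, 53.8 and 44.4 M in obese replicates 1 to 4 and 39.0, 47.9, 47.4 and 53.7 M in lean replicates 1 to 4. The comparison asks which tumour genes differ in expression between obese and lean hosts. Values below are mean ± SD in CPM (n = 4 tumours per group, obese first), and log2 changes are obese minus lean ± SE.

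Tumours of obese mice held more RNA of genes of epithelial-mesenchymal transition, of cell division and of glycolysis, and less RNA of keratins, of B cell markers and of nuclear genes of oxidative phosphorylation. These 6 lists passed camera with a preset correlation, while their adjusted p was 0.643 to 0.681 with an estimated correlation. Vim, an intermediate filament of mesenchymal cells (ENSMUSG00000026728, chromosome 2, 13573927 to 13582826), rose by a log2 change of 3.60 ± 0.34, from a lean mean of 529 ± 150.3 to 6408 ± 2467 CPM (edgeR adjusted p = 0.000276). Krt17, a keratin of basal epithelium, stood at 0.981 ± 1.05 against 75.1 ± 63.1 CPM (log2 change −6.20 ± 1.2, edgeR adjusted p = 0.00415). Of 14887 tested genes, 8819 (59.2%) passed the threshold, 4598 higher and 4221 lower in obese tumours. At least a 2-fold difference was seen for 2568 of the higher and 3168 of the lower genes, and at least a 16-fold difference for 242 and 310. The values of the 4 obese tumours lay all above or all below those of the 4 lean tumours for 57.0% of tested genes, where chance gives 2.86%. On the first principal component, which held 88.6% of the variance, obese replicate 3 lay at 12.9, the other obese tumours from −136 to −96.5 and the lean tumours from 70.2 to 93.7.

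**Figure D1:**
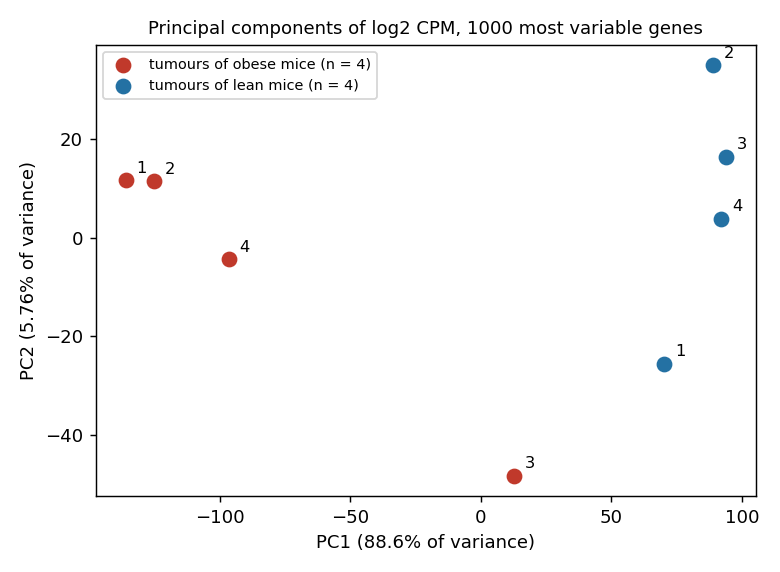
Principal components of the log2 CPM of the 1000 most variable tested genes, with 1 point per tumour; the horizontal axis is the first component (88.6% of the variance) and the vertical axis the second (5.76%), both in component scores. Obese and lean tumours are apart along the horizontal axis, and obese replicate 3 (12.9) lies between the other 3 obese tumours and the lean tumours.

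Genes of the mammary epithelium were lower as groups. Of 15 tested basal and myoepithelial genes 12 fell and 0 rose (adjusted over the list alone, 13 and 0), with a median log2 change of −4.37 (camera adjusted p = 0.00328, and adjusted p = 0.643 with an estimated correlation). Krt19, a keratin of simple epithelium (ENSMUSG00000020911, chromosome 11, 100140810 to 100148665), fell from 38.8 ± 33.9 in lean to 0.197 ± 0.153 CPM in obese tumours, a log2 change of −7.73 ± 1.37 (edgeR adjusted p = 0.00293). Col17a1, a hemidesmosome collagen, stood at 4.26 ± 2.33 against 181 ± 219 CPM and fell (−5.40 ± 1.10, or −4.13 without lean replicate 2, which held 499.9 CPM). Of 22 keratin genes 11 fell and 0 rose (10 and 0 adjusted over the list alone). The keratin median was −3.96 (camera adjusted p = 0.00309, and adjusted p = 0.643 with an estimated correlation). Of 20 luminal genes 4 fell and 0 rose (2 and 0 adjusted over the list alone). The luminal median was −3.33 (camera adjusted p = 0.000589, and adjusted p = 0.643 with an estimated correlation). The 4 that fell were Krt19, the tight junction gene Cldn4 (−4.60 ± 1.15), the epithelial transcription factor gene Elf3 (−2.44 ± 0.70) and Krt8 (−1.46 ± 0.48). The milk protein list had a median of −3.09 over 12 genes, of which 3 fell and 0 rose (2 and 0 adjusted over the list alone, camera adjusted p = 0.00534, and adjusted p = 0.643 with an estimated correlation). Lalba, a milk whey protein gene, fell (−4.74 ± 1.15). Obese replicate 3 stood apart in these lists, and without it 19 luminal genes fell with a median of −7.16 and 11 milk protein genes fell with a median of −7.60, while Cldn4 changed by −6.40 and Lalba by −6.39. The luminal median was −5.87 with limma-voom, and the milk protein median −5.71. The epithelial genes Epcam, Krt18 and Esrp1, an RNA splicing factor of epithelium, were chosen after their values were seen. In the full set they did not pass (edgeR adjusted p = 0.101, 0.133 and 0.176), with log2 changes of −3.24, −3.53 and −3.09. Without that tumour they did (edgeR adjusted p = 0.000314, 0.00168 and 0.000486), with changes of −6.96, −7.94 and −8.21. Over all alternatives their adjusted p spanned 3.0e-05 to 0.180, 0.000126 to 0.232 and 5.54e-05 to 0.283. Krt8's call ended without obese replicate 4 (edgeR adjusted p = 0.0591), without lean replicate 1 (0.0647) and with offsets for GC content and gene length (0.0944), within a range of 0.00134 to 0.0944. Keratinocyte and hair follicle markers fell in 5 of 6 genes and rose in 0 (6 and 0 adjusted over the list alone). The keratinocyte median was −4.999 (camera adjusted p = 0.0380, and adjusted p = 0.643 with an estimated correlation). Lgals7 stood at 6.81 ± 6.67 against 113 ± 55.0 CPM. The keratinocyte call ended without obese replicate 3 (0.0533) and without lean replicate 2 (0.0591). Of the other settings, it ended with upper quartile factors (0.0772), with library size only (0.0739), with limma-voom and quality weights (0.0894), with 1 surrogate variable (0.0728) and with offsets for GC content and gene length (0.0508), over all alternatives 0.0135 to 0.746.

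Genes of epithelial-mesenchymal transition were higher, while fibroblast and collagen genes went both ways. Of 21 transition genes 12 rose and 2 fell, with a median of 2.11 (camera adjusted p = 0.00270, and adjusted p = 0.643 with an estimated correlation), or 1.37 without obese replicate 1. Prrx1, a homeobox transcription factor of mesenchyme, stood at 216 ± 52.5 against 8.47 ± 4.73 CPM (4.67 ± 0.47, edgeR adjusted p = 0.000321). Axl, a receptor tyrosine kinase, stood at 926 ± 189 against 164 ± 9.23 CPM (2.49 ± 0.17, edgeR adjusted p = 0.000159). Itga5, a fibronectin receptor chain, stood at 319 ± 71.4 against 59.6 ± 9.11 CPM (2.42 ± 0.20). Of 19 matrix metalloprotease and invasion genes 10 rose and 1 fell. The metalloprotease median was 1.301 (camera adjusted p = 0.0204, and adjusted p = 0.643 with an estimated correlation). Mmp14, a membrane-bound metalloprotease, stood at 535 ± 191 against 124 ± 16.8 CPM. Of 23 fibroblast and matrix genes 7 rose and 10 fell. The fibroblast median was −0.65 (camera adjusted p = 0.498), or −0.28 without lean replicate 2 and −0.05 with limma-voom and quality weights. Col6a3 (4.21 ± 0.58) and Col6a1 (3.54 ± 0.54), chains of type VI collagen, rose and Thy1 (−1.40 ± 0.25) fell. Of 37 collagen genes 7 rose and 14 fell. The collagen median was −1.499 (camera adjusted p = 0.0410, and adjusted p = 0.643 with an estimated correlation). Without obese replicate 3, 22 of 40 collagen genes fell and 8 rose, with a median of −2.22. Col5a3 stood at 621 ± 303 against 26.2 ± 15.6 CPM. The collagen call ended without obese replicate 3 (0.0533), without lean replicate 2 (0.0800) and without lean replicate 3 (0.0530). It also ended with DESeq2's size factors (0.0584), with upper quartile factors (0.131), with library size only (0.123), with a filter of 1 CPM in 4 tumours (0.0754), with limma-voom (0.0539), with limma-voom and quality weights (0.170), with 1 surrogate variable (0.0854) and with offsets for GC content and gene length (0.0660), over all alternatives 0.00900 to 0.746.

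**Figure D2:**
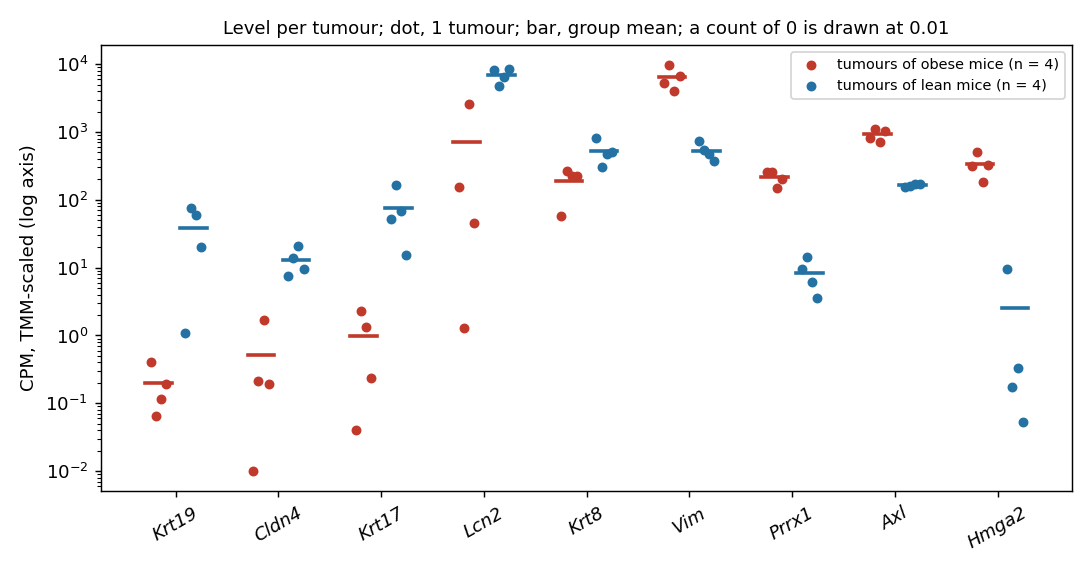
Level of 9 genes in each tumour in CPM on a log axis, with 1 dot per tumour and a bar at each group mean; the count of 0 for Cldn4 in obese replicate 1 is drawn at 0.01 CPM. Vim, Prrx1, Axl and Hmga2 lie higher in all 4 obese tumours than in all 4 lean tumours, and Krt19, Cldn4, Krt17, Krt8 and Lcn2 lie lower.

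Among the 12 largest rises, Hmga2, a chromatin protein of embryonic cells (ENSMUSG00000056758, chromosome 10, 120361275 to 120476469), stood at 334 ± 136 against 2.56 ± 4.76 CPM, a log2 change of 7.04 ± 1.68 (edgeR adjusted p = 0.00937). Nppb, a natriuretic peptide gene, stood at 31.1 ± 24.5 against 0.255 ± 0.485 CPM (6.98 ± 1.65). Without lean replicate 1 these changes were 10.82 and 11.03. Tdrd1 (7.60) and Tex11 (7.27), genes of the germ line, and Ereg (6.90), a ligand of the epidermal growth factor receptor, also rose. Further genes of that group were Gpr149 (7.57), Fbxl16 (7.28), Esx1 (6.71), Nxf3 (6.70), Zic2 (6.67) and Gprin1 (6.62). Leaving out lean replicate 1 also raised the changes of Gpr149, Fbxl16, Tdrd1, Tex11, Ereg, Nxf3, Zic2 and Gprin1, to 10.26, 9.18, 10.60, 10.88, 9.63, 9.15, 9.54 and 8.77. These genes, Hmga2, Nppb and Esx1 were all highest in lean replicate 1 among the lean tumours. There Hmga2 stood at 9.70 CPM (other lean tumours 0.053 to 0.332) and Tdrd1 at 1.23 (0.018 to 0.077). Tex11 stood at 1.33 (0 to 0.039) and Nxf3 at 4.05 (0.053 to 0.479). Their lean means thus rest largely on 1 tumour, and a shared source in it was not tested. Among the 12 largest falls, the glutathione peroxidase gene Gpx2 stood at 0.0591 ± 0.0424 against 118 ± 213 CPM (−10.75 ± 2.54), with 437 CPM in lean replicate 2. The laminin gene Lama1 stood at 0.0990 ± 0.168 against 49.3 ± 80.2 CPM (−8.80 ± 2.03), with 169 CPM in that tumour. Krt19 (−7.73), Ntrk3 (−7.70), Cnn1 (−7.62), Ackr4 (−7.30), Fmod (−6.79), Id4 (−6.74), Apoc1 (−6.73) and Moxd1 (−6.69) also fell. So did Cyp24a1, whose product breaks down vitamin D, and the cartilage collagen gene Col9a2. The log2 changes of the last pair were −6.78 and −6.71, and without obese replicate 3 they were −10.48 and −11.04. Without that tumour those of Lama1, Fmod, Ntrk3, Id4 and Moxd1 were −11.36, −9.17, −8.91, −8.05 and −7.89. Much of the lean mean came from lean replicate 2 for several of these genes, and without it the changes of Gpx2, Lama1, Ntrk3, Cnn1, Ackr4, Fmod, Id4, Apoc1 and Moxd1 shrank to −7.46, −6.45, −5.53, −5.85, −5.42, −5.34, −5.38, −5.67 and −4.92. With limma-voom, Gpx2 (limma adjusted p = 0.156), Lama1 (0.0517), Krt19 (0.0538), Ntrk3 (0.0631) and Cnn1 (0.0825) missed the threshold. Over all alternatives their adjusted p ran from 0.00559 to 0.156, 5.88e-06 to 0.0517, 6.61e-11 to 0.0853, 1.95e-06 to 0.0631 and 1.39e-07 to 0.0825.

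Of the 5 genes with the highest mean count, the elongation factor gene Eef1a1, which has pseudogenes, stood at 14712 ± 1314 against 6077 ± 698 CPM (1.28 ± 0.14, edgeR adjusted p = 0.000403). The chaperone gene Hsp90ab1 stood at 6239 ± 458 against 3115 ± 798 CPM (1.002 ± 0.19, edgeR adjusted p = 0.00335). Igfbp5 (1092 ± 2134 against 8964 ± 3559 CPM), the transferrin gene Trf (1008 ± 1742 against 8323 ± 480.3 CPM) and Lcn2 (706 ± 1278 against 6947 ± 1716 CPM) did not pass. Their log2 changes were −3.04 ± 1.91, −3.05 ± 1.37 and −3.30 ± 1.71 (edgeR adjusted p = 0.194, 0.0850 and 0.125). Without obese replicate 3 these changes were −8.48, −5.90 and −6.68 and passed (edgeR adjusted p = 0.000530, 0.000843 and 0.00471). Over all alternatives the adjusted p of these 3 genes ran from 9.2e-05 to 0.299, 5.99e-05 to 0.162 and 0.000217 to 0.218.

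Genes of cell division and of sugar and sterol metabolism were higher. Of 32 cell cycle genes 28 rose and 2 fell, with a median of 1.04 (camera adjusted p = 0.000134, and adjusted p = 0.681 with an estimated correlation). Top2a, a topoisomerase of dividing cells, stood at 697 ± 138 against 165 ± 76.9 CPM (2.08 ± 0.32). The cyclin gene Ccna2 stood at 294 ± 49.9 against 88.5 ± 32.0 CPM and the transcription factor gene Foxm1 at 154 ± 43.5 against 42.2 ± 10.8 CPM. Mcm2, a replicative helicase subunit, rose (1.25 ± 0.16). Of 17 glycolysis genes 13 rose and 1 fell (14 and 1 adjusted over the list alone). The glycolysis median was 1.37 (camera adjusted p = 0.000223, and adjusted p = 0.643 with an estimated correlation). The glucose transporter gene Slc2a1 stood at 395 ± 140.4 against 61.3 ± 9.67 CPM and Gpi1 at 688 ± 104 against 267 ± 19.1 CPM. Of 17 hypoxia response genes 13 rose and 2 fell (13 and 3 adjusted over the list alone). The hypoxia median was 1.67 (camera adjusted p = 0.00309, and adjusted p = 0.643 with an estimated correlation). Adm, a vasodilator peptide gene, stood at 128 ± 55.6 against 5.51 ± 2.45 CPM and Ero1l at 238 ± 53.9 against 45.0 ± 10.6 CPM. Of 22 cholesterol synthesis genes 17 rose and 1 fell. The cholesterol median was 0.90 (camera adjusted p = 0.00111, and adjusted p = 0.643 with an estimated correlation). Those that rose include Msmo1 (1.99 ± 0.27) and Sc5d (1.13 ± 0.13). Ribosomal protein genes rose in 35 and fell in 7 of 83 cases (34 and 6 adjusted over the list alone). The ribosomal median was 0.29 (camera adjusted p = 0.00309, and adjusted p = 0.643 with an estimated correlation), or 0.07 with upper quartile factors, 0.10 with library size only, 0.18 with limma-voom and quality weights and 0.66 with offsets for GC content and gene length. Rps2 (1.46 ± 0.11) and Rpl35a (1.98 ± 0.17) rose, although reads of these genes can be shared with their pseudogenes. Of 38 proteasome genes 18 rose and 3 fell. The proteasome median was 0.28 (camera adjusted p = 0.0432, and adjusted p = 0.784 with an estimated correlation). Psmd8 stood at 412 ± 90.3 against 171 ± 11.7 CPM. The proteasome call ended without obese replicate 1 (0.0685), without obese replicate 3 (0.0684), without lean replicate 2 (0.0975) and without lean replicate 3 (0.0539). Among the other settings it ended with DESeq2's size factors (0.0584), with upper quartile factors (0.186), with library size only (0.163), with a filter of 1 CPM in 4 tumours (0.125), with limma-voom and quality weights (0.0776) and with 1 surrogate variable (0.0728), over all alternatives 0.00680 to 0.845. Its median was 0.07 with upper quartile factors and 0.10 with library size only. Without obese replicate 3, 5 proteasome genes fell.

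Nuclear genes of oxidative phosphorylation fell in 50 and rose in 2 of 78 cases. The oxidative phosphorylation median was −0.78 (camera adjusted p = 1.99e-05, and adjusted p = 0.643 with an estimated correlation), or −0.44 with offsets for GC content and gene length. Ndufb11 and Ndufa11, subunits of complex I, stood at 59.9 ± 19.6 against 204 ± 35.1 CPM (−1.77 ± 0.24) and 54.6 ± 11.5 against 119 ± 10.6 CPM (−1.13 ± 0.16). The latter changed by −0.45 with those offsets. Of 20 fatty acid synthesis genes 11 fell and 0 rose. The fatty acid synthesis median was −0.86 (camera adjusted p = 0.0293, and adjusted p = 0.643 with an estimated correlation). The desaturase genes Fads1 (−1.62 ± 0.26) and Fads2 (−1.62 ± 0.29) fell, and the lipid regulator gene Srebf1 stood at 225 ± 210.1 against 1471 ± 570.3 CPM. The fatty acid synthesis call ended without obese replicate 3 (0.0533) and without lean replicate 2 (0.0594), and with limma-voom and quality weights (0.0644), over all alternatives 0.00789 to 0.693. Of 23 fatty acid oxidation and PPAR target genes 11 fell and 2 rose. The fatty acid oxidation median was −0.63 (camera adjusted p = 0.0485, and adjusted p = 0.643 with an estimated correlation). The mitochondrial enzymes Cpt2 (−0.79 ± 0.13) and Acaa2 (−0.86 ± 0.15) fell, while Angptl4 (2.47 ± 0.46), an inhibitor of lipoprotein lipase, and the nuclear receptor gene Ppard (1.32 ± 0.25) rose. The fatty acid oxidation call ended without obese replicate 1 (0.0938), without obese replicate 3 (0.123), without lean replicate 1 (0.0791) and without lean replicate 4 (0.0541). It was lost too with DESeq2's size factors (0.0507), with upper quartile factors (0.0662), with library size only (0.0671), with no filter (0.0718), with limma-voom and quality weights (0.104), with 1 surrogate variable (0.107) and with offsets for GC content and gene length (0.0543), over all alternatives 0.0112 to 0.746.

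Lymphocyte markers were lower. Of 13 B and plasma cell markers 12 fell and 0 rose. The B cell median was −3.82 (camera adjusted p = 0.000134, and adjusted p = 0.643 with an estimated correlation). The B cell surface gene Ms4a1 stood at 0.194 ± 0.0621 against 4.45 ± 2.26 CPM. Of 24 T and NK cell markers 14 fell and 0 rose. The T and NK median was −1.45 (camera adjusted p = 0.00328, and adjusted p = 0.710 with an estimated correlation, and fry adjusted p = 0.0704). T and NK scores per tumour overlapped between the groups (exact permutation p = 0.0571, adjusted 0.0895), while B cell scores did not (0.0286, adjusted 0.0480). The T cell kinase gene Lck stood at 11.8 ± 4.75 against 44.3 ± 15.9 CPM and Cd4 at 10.1 ± 3.19 against 25.9 ± 5.89 CPM. Eomes, a transcription factor of cytotoxic lymphocytes, fell (−2.04 ± 0.38). Antigen presentation genes fell in 10 and rose in 0 of 17 cases. The antigen presentation median was −1.58 (camera adjusted p = 0.0293, and adjusted p = 0.784 with an estimated correlation, and fry adjusted p = 0.175). Antigen presentation scores per tumour overlapped too (exact permutation p = 0.0857, adjusted 0.126). Cd74, the invariant chain of class II molecules, stood at 918 ± 791 against 6351 ± 2851 CPM. H2-K1, a class I gene with close paralogs, stood at 1232 ± 557 against 4818 ± 1987 CPM with overlapping groups. The antigen presentation call ended without lean replicate 1 (0.0598) and with offsets for GC content and gene length (0.0620), over all alternatives 0.000484 to 0.845. Of 4 tested lymph node stroma markers, too few for a list test, 4 fell and 0 rose, with Madcam1 at 0.0631 ± 0.0394 against 0.469 ± 0.178 CPM. Of 3 tested erythrocyte markers 1 fell and 0 rose (Ermap, −2.63 ± 0.56), or 2 and 0 without obese replicate 3.

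Myeloid lists did not pass camera, and their members went different ways. Of 20 macrophage and monocyte markers 8 rose and 2 fell. The macrophage median was −0.25 and the mean was 0.31 (camera adjusted p = 0.550). With offsets for GC content and gene length the median turned to 0.16, and it was −0.12 without obese replicate 1, −0.10 without obese replicate 2 and −0.07 without lean replicate 4. The integrin gene Itgam stood at 177 ± 30.3 against 22.3 ± 8.26 CPM and the scavenger receptor gene Msr1 at 93.9 ± 44.1 against 17.7 ± 6.54 CPM. Of 16 lipid-associated macrophage genes 6 rose and 1 fell, or 7 and 2 without obese replicate 3. The lipid-associated macrophage median was 0.61 (camera adjusted p = 0.141, and fry adjusted p = 0.0135), or 0.28 without obese replicate 4 and 0.39 without lean replicate 4. The protease gene Ctsl stood at 1695 ± 312 against 211 ± 47.3 CPM and Gpnmb at 249.8 ± 192 against 15.3 ± 11.5 CPM, while Fabp5, a fatty acid binding protein gene, fell (−1.88 ± 0.37). Neutrophil markers (10 tested) rose in 3 and fell in 1 cases, or 3 and 2 without obese replicate 3. The neutrophil median was 1.84 (camera adjusted p = 0.498), or 0.42 without obese replicate 1. Clec4d (3.79 ± 0.81) and Mmp8 (4.38 ± 0.98, or 3.15 without obese replicate 1) rose and the lactoferrin gene Ltf fell (−4.19 ± 1.04, or −6.27 without obese replicate 3). Dendritic cell markers (13 tested) rose in 2 and fell in 4 cases. The dendritic cell median was −0.56 (camera adjusted p = 0.298), or −0.89 without obese replicate 4. Fscn1 (2.54 ± 0.22) and Ly75 (1.84 ± 0.19) rose and Batf3 fell (−2.01 ± 0.45, or −1.31 with offsets for GC content and gene length). Of 10 mast cell and eosinophil markers 6 rose and 3 fell (7 and 3 adjusted over the list alone). The mast cell and eosinophil median was 2.09 (camera adjusted p = 0.543). The mast cell protease gene Cpa3 rose (3.36 ± 0.80) and the eosinophil granule gene Prg2 fell (−5.50 ± 0.96, or −7.03 without obese replicate 4).

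Cytokine and checkpoint lists did not pass camera in the full set either. Of 23 inflammatory cytokine and NF-kB genes 10 rose and 1 fell. The inflammatory median was 2.52 (camera adjusted p = 0.141), or 0.64 without obese replicate 1. Without obese replicate 3, 3 of these genes fell. Ccl2, a monocyte attractant, stood at 269 ± 145 against 16.3 ± 10.3 CPM and Ccl7 at 141 ± 59.7 against 21.5 ± 11.9 CPM. The inflammatory list passed without obese replicate 2 (0.0396), over all alternatives 0.0396 to 0.863. Chemokine genes (30 tested) rose in 9 and fell in 8 cases. The chemokine median was 0.10, −0.11 with upper quartile factors and −0.08 with library size only (camera adjusted p = 0.975). With no filter it was −0.54, and with offsets for GC content and gene length 0.31. Leaving out 1 tumour moved it to 0.15 without obese replicate 2, 0.43 without lean replicate 1, −0.07 without lean replicate 2, 0.20 without lean replicate 3 and 0.15 without lean replicate 4. Cxcl12 fell (−3.48 ± 0.72). Of 24 interferon response genes 9 rose and 0 fell (8 and 0 adjusted over the list alone), or 7 and 1 without obese replicate 3. The interferon median was 0.17, −0.04 with upper quartile factors (camera adjusted p = 0.179). Single tumours moved it too, to 0.26 without obese replicate 2, 0.30 without lean replicate 1, −0.12 without lean replicate 2 and 0.41 without lean replicate 4. The antiviral gene Rsad2 stood at 281 ± 106 against 53.7 ± 22.5 CPM. The interferon list passed without lean replicate 4 (0.0463), over all alternatives 0.0463 to 0.874. Of 15 immune checkpoint genes 5 rose and 2 fell. The checkpoint median was 0.25 (camera adjusted p = 0.498), or −0.13 with limma-voom and quality weights. With 1 tumour fewer it was 0.04 without obese replicate 1, 0.09 without obese replicate 4 and −0.00197 without lean replicate 2. Cd274, which encodes the ligand PD-L1, stood at 94.0 ± 29.1 against 16.7 ± 5.74 CPM. Lag3, a receptor of activated lymphocytes, stood at 6.44 ± 2.58 against 31.8 ± 13.5 CPM.

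Vessel and nerve markers were lower. Of 12 pericyte and smooth muscle markers 9 fell and 0 rose. The pericyte median was −2.41 (camera adjusted p = 0.0176, and adjusted p = 0.643 with an estimated correlation). Notch3 stood at 4.71 ± 4.41 against 65.5 ± 21.0 CPM and Tagln, a smooth muscle actin-binding protein gene, at 6.78 ± 3.29 against 42.5 ± 25.4 CPM. Tagln is 1 of 5 among the 12 listed pericyte genes that the basal and myoepithelial list also holds. The falls of these lists are therefore not independent. The pericyte call ended without obese replicate 3 (0.0572) and with limma-voom and quality weights (0.0776), over all alternatives 0.00508 to 0.746. Of 19 endothelial markers 10 fell and 1 rose. The endothelial median was −0.90 (camera adjusted p = 0.0226, and adjusted p = 0.6998 with an estimated correlation). Plvap (−1.41 ± 0.16, or −0.85 with offsets for GC content and gene length) and the growth factor receptor gene Flt1 (−1.18 ± 0.19) fell, and Eng, a TGF-beta co-receptor gene, rose (1.77 ± 0.17). The endothelial call ended without obese replicate 3 (0.0861) and without lean replicate 2 (0.0648). In addition it ended with limma-voom and quality weights (0.0925), with 1 surrogate variable (0.0699) and with offsets for GC content and gene length (0.0522), over all alternatives 0.00572 to 0.845. Of 9 nerve and Schwann cell markers 5 fell and 0 rose. The Schwann cell median was −2.69 (camera adjusted p = 0.00855, and adjusted p = 0.643 with an estimated correlation), or −4.51 with limma-voom and quality weights. The myelin gene Mbp stood at 14.2 ± 5.34 against 38.6 ± 9.65 CPM. Adipocyte markers (19 tested) rose in 1 and fell in 4 cases (0 and 1 adjusted over the list alone). The adipocyte median was −0.87 (camera adjusted p = 0.0663). It was −2.63 without obese replicate 4 and −0.47 without lean replicate 2, and 2 adipocyte markers fell without obese replicate 3. The insulin-responsive glucose transporter gene Slc2a4 stood at 0.730 ± 0.638 against 31.3 ± 38.3 CPM, a log2 change of −5.40, or −4.12 without lean replicate 2. The adipocyte list passed without obese replicate 4 (0.00215) and without lean replicate 4 (0.0285), and with limma-voom (0.0447), over all alternatives 0.00215 to 0.874. Skeletal muscle markers (18 tested) rose in 1 and fell in 1 cases (0 and 0 adjusted over the list alone), while 10 fell and 0 rose without obese replicate 3. The muscle median was −3.20 (camera adjusted p = 0.0788), or −4.29 without obese replicate 3. The muscle list passed without lean replicate 2 (0.0248) and without lean replicate 3 (0.0453), over all alternatives 0.0248 to 0.863. The myoglobin gene Mb fell (−3.16 ± 0.94, or −4.66 without obese replicate 3), a call that ended without obese replicate 4 (edgeR adjusted p = 0.0581, over all alternatives 6.46e-05 to 0.0581).

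**Figure D3:**
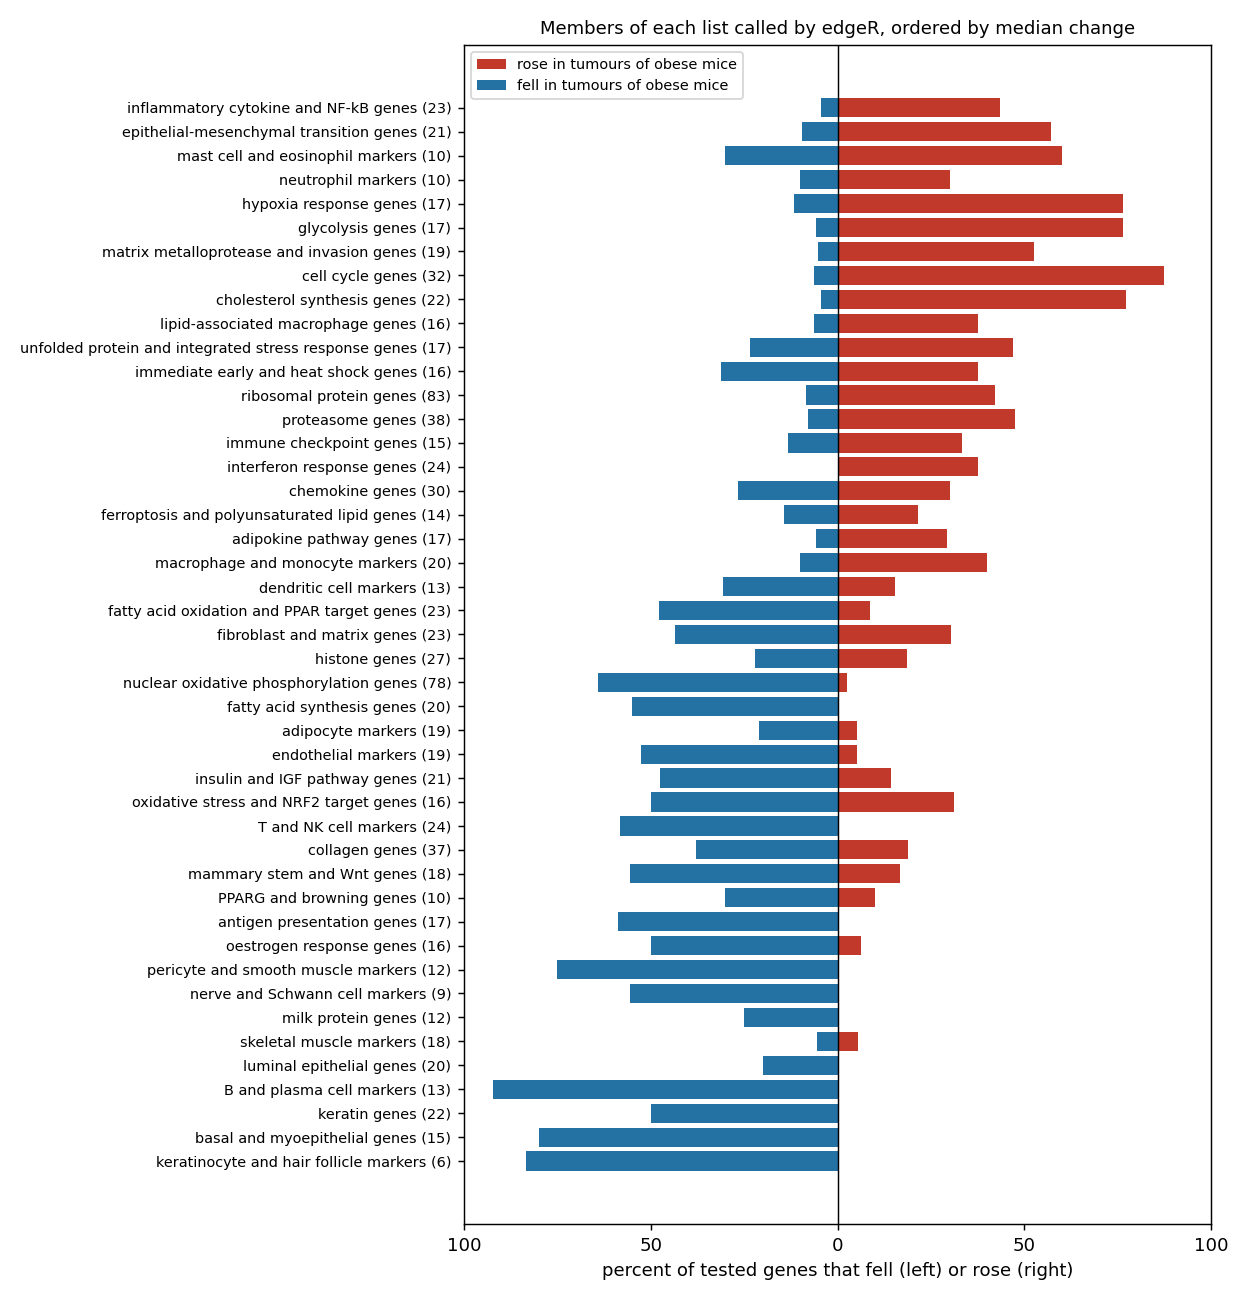
Percent of tested genes of each list that fell (bars to the left) or rose (bars to the right) in tumours of obese mice by edgeR, for lists with at least 5 tested genes, ordered by median log2 change; the number of tested genes stands in brackets. Cell cycle genes rose in 28 of 32 cases and B and plasma cell markers fell in 12 of 13; the medians of the chemokine, interferon and ferroptosis lists change sign with upper quartile factors.

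Among hormone and growth lists, oestrogen response genes fell in 8 and rose in 1 of 16 cases. The oestrogen median was −1.97 (camera adjusted p = 0.0268, and adjusted p = 0.643 with an estimated correlation). This call ended with upper quartile factors (0.0648), with library size only (0.0586) and with limma-voom and quality weights (0.0612), over all alternatives 0.00759 to 0.643. Wnt4, a Wnt ligand downstream of progesterone, stood at 0.0445 ± 0.0499 against 4.75 ± 4.12 CPM and Cited1 at 0.143 ± 0.0962 against 10.6 ± 8.29 CPM. Of 18 mammary stem and Wnt genes 10 fell and 3 rose. The Wnt median was −1.56 (camera adjusted p = 0.0410, and adjusted p = 0.643 with an estimated correlation). Dkk3 fell (−4.09 ± 0.60) and the hyaluronan receptor gene Cd44 rose (1.95 ± 0.29). The Wnt call ended without obese replicate 3 (0.0541). This list also lost its call with DESeq2's size factors (0.0564), with upper quartile factors (0.0995), with library size only (0.0945), with a filter of 1 CPM in 4 tumours (0.0774), with limma-voom and quality weights (0.0809), with 1 surrogate variable (0.0629) and with offsets for GC content and gene length (0.0724), over all alternatives 0.00789 to 0.693. Of 21 insulin and IGF pathway genes 3 rose and 10 fell. The insulin and IGF median was −0.99 (camera adjusted p = 0.133, and fry adjusted p = 0.0341). Igf1r, the IGF1 receptor gene, stood at 72.2 ± 40.6 against 8.68 ± 5.76 CPM and Igfbp6 at 31.9 ± 16.8 against 3.03 ± 1.10 CPM. Igfbp7 stood at 49.7 ± 16.3 against 212 ± 23.7 CPM. Of 17 adipokine pathway genes 5 rose and 1 fell (4 and 1 adjusted over the list alone), or 5 and 2 without obese replicate 3. The adipokine median was −0.04 and the mean was 0.01 (camera adjusted p = 0.975). That median turned sign in several settings, and it was 0.03 without obese replicate 1, 0.23 without obese replicate 2, 0.16 without obese replicate 3, −0.10 without obese replicate 4, −0.10 without lean replicate 1, 0.09 without lean replicate 2 and 0.00835 without lean replicate 4. Cdh13, an adiponectin receptor gene, stood at 113 ± 45.5 against 9.28 ± 3.40 CPM, while the apelin receptor gene Aplnr fell (−1.62 ± 0.31). PPARG and browning genes (10 tested) rose in 1 and fell in 3 cases (0 and 3 adjusted over the list alone). The browning median was −1.57 (camera adjusted p = 0.0788, and fry adjusted p = 0.0106), and 5 browning genes fell without obese replicate 3. The coactivator gene Ppargc1a stood at 0.138 ± 0.119 against 1.67 ± 0.794 CPM. The browning list passed without obese replicate 4 (0.0401), over all alternatives 0.0106 to 0.746.

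Stress lists did not pass camera in the full set. Of 17 unfolded protein and integrated stress response genes 8 rose and 4 fell (8 and 5 adjusted over the list alone). The unfolded protein median was 0.57 (camera adjusted p = 0.445, and fry adjusted p = 0.0388, over all alternatives 0.0388 to 0.863). That median was 0.32 without lean replicate 2 and 0.35 with upper quartile factors. The asparagine synthetase gene Asns stood at 417 ± 88.7 against 30.6 ± 8.38 CPM and Atf4 at 496 ± 47.2 against 262 ± 24.3 CPM. Of 16 oxidative stress and NRF2 target genes 5 rose and 8 fell. The NRF2 median was −1.01 (camera adjusted p = 0.451). Srxn1 rose (2.72 ± 0.29) and Cbr3 fell (−3.30 ± 0.51). Ferroptosis and polyunsaturated lipid genes (14 tested) rose in 3 and fell in 2 cases (2 and 2 adjusted over the list alone). The ferroptosis median was 0.01 (−0.20 with upper quartile factors and −0.18 with library size only) and the mean was −0.15 (camera adjusted p = 0.975). Near 0, the ferroptosis median moved to −0.13 without obese replicate 1, 0.04 without obese replicate 2, 0.08 without obese replicate 3, 0.04 without obese replicate 4, 0.02 without lean replicate 1, 0.05 without lean replicate 2, 0.02 without lean replicate 3 and 0.03 without lean replicate 4. The transferrin receptor gene Tfrc rose (1.59 ± 0.31) and Alox12 fell (−2.34 ± 0.44). Immediate early and heat shock genes (16 tested), which also respond to handling of tissue, rose in 6 and fell in 5 cases. The immediate early median was 0.33 and the mean was −0.02 (camera adjusted p = 0.783). With limma-voom and quality weights that median turned to −0.19, and it was 0.00877 without obese replicate 1 and 0.11 without lean replicate 2. Ier3 stood at 274 ± 140.2 against 72.6 ± 22.98 CPM, Egr1 at 10.2 ± 8.80 against 82.4 ± 20.7 CPM and Hspa1b at 9.98 ± 4.56 against 49.3 ± 20.9 CPM. Histone genes (27 tested) rose in 5 and fell in 6 cases (4 and 5 adjusted over the list alone). The histone median was −0.66 (camera adjusted p = 0.455), or −0.36 without obese replicate 3, −0.26 without lean replicate 3 and −0.28 without lean replicate 4. It was −1.27 with a filter of 1 CPM in 4 tumours and −1.09 with limma-voom and quality weights. Closer to the middle, it was −0.37 with limma-voom, −0.21 with offsets for GC content and gene length and −0.16 with no filter. Hist1h2bc, one of a family of near-identical genes, stood at 21.3 ± 12.7 against 192 ± 82.9 CPM. The histone list passed without lean replicate 2 (0.0460), over all alternatives 0.0460 to 0.992. The 4 genes of the Y-linked list and the mitochondrially encoded protein genes had a count of 0 in all libraries and were not tested.

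In all, 25 of 45 lists passed camera with the preset correlation, 8 higher and 17 lower. With an estimated correlation 0 passed, 0 had an unadjusted p under 0.05 and the lowest adjusted p was 0.643. Fry passed 27 lists, 23 of them also passed by camera. For 30 of 47 lists with a tested gene the number of members that rose and fell was the same adjusted over the list alone. The others are given beside their lists. Per-tumour list scores reached the smallest exact permutation p (0.0286, adjusted 0.0480) for 28 of 47 lists. The groups also did not overlap for 57.0% of all tested genes, so this count is not particular to the lists.

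Total counts did not differ detectably between groups (47.6 ± 17.2 against 47.0 ± 6.09 M, exact permutation p = 0.971). Fewer genes reached 10 counts in obese tumours (13858 ± 754 against 15094 ± 15.7, exact permutation p = 0.0286). TMM factors were 0.938 ± 0.0217 and 1.07 ± 0.0225 (exact permutation p = 0.0286). With upper quartile factors 3612 genes were higher and 5145 lower, and the median change of all tested genes moved from −0.04 to −0.25. Spearman correlations over genes were 0.926 to 0.984 within obese, 0.930 to 0.988 within lean and 0.748 to 0.916 between groups. Pairs with obese replicate 3 gave 0.926 to 0.947 within obese and 0.880 to 0.916 between groups. The other pairs began at 0.968 within obese and ended at 0.810 between groups. Genes are not independent replicates. The distance between group centres in the space of the 1000 most variable genes was 2.26 times the mean distance within groups.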

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

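The tests of a larger share of stroma, of another tumour cell population, of an exchanged library and of depth were chosen after the results they measure were seen. The same holds for the shuffling of genes over chromosomes, given further below. The others were chosen before their own results, although the offsets for GC content and gene length were added after the data were seen. In 368 groups of 4 tumours, 24 had a tumour far from the other 3 by Dixon's ratio, where chance alone gives about 1 in 20, or 18.4. They came from lean replicate 1 (8), lean replicate 2 (7), obese replicate 3 (4), obese replicate 1 (3) and obese replicate 2 (2). The groups share the same tumours and are not independent of each other, so the chance rate is only a guide.

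In lean replicate 1, log2 CPM stood at −0.84 for Gpr149 (others −4.06 to −4.02), 0.0348 for Nppb (−4.57 to −4.03), −1.12 for Zic2 (−4.57 to −4.02), 2.76 for Igf2bp2 (0.16 to 0.42), 6.85 for Fads2 (7.70 to 7.86) and 8.14 for Ctsl (7.53 to 7.58). Its list score was 6.64 for glycolysis (others 6.18 to 6.26) and −0.17 for lymph node stroma (0.18 to 0.21). Lean replicate 2 had log2 CPM of 2.184 for Batf3 (others 2.84 to 2.86), 10.87 for H2-K1 (12.44 to 12.61) and 3.03 for Cd274 (4.24 to 4.33). Its list scores were 2.48 for T and NK cells (others 3.61 to 3.83), 5.62 for macrophages (6.23 to 6.35), 8.25 for antigen presentation (9.59 to 9.81) and 4.57 for immediate early and heat shock genes (5.26 to 5.38). Obese replicate 3 had log2 CPM of 2.78 for Zic2 (others 3.60 to 3.74), 6.48 for Ndufb11 (5.58 to 5.69) and 10.08 for Rps2 (10.34 to 10.36), and a score of 2.33 for mammary stem and Wnt genes (1.26 to 1.44). In obese replicate 1 log2 CPM was 5.87 for Krt8 (others 7.79 to 8.06), 6.49 for Clec4d (3.99 to 4.4) and 8.92 for Ier3 (7.61 to 7.74). In obese replicate 2 it was 0.95 for Tagln (others 3.01 to 3.19), and the 10 most abundant genes took 5.49% of its counts (others 4.71 to 4.83%).

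Chance is argued against for the number of genes but not excluded. Of the 35 splits of the tumours into 4 and 4, 1, the real one with 8819, called as many, and the highest of the others called 0. That is the smallest share 35 splits can give, and every other split mixes obese and lean tumours. Chance cannot be excluded for the number of lists, since 7 of the 35 splits called at least the real 25, and the highest of the others called 31. For the distance between group centres, 1 of the 35 splits was as large as the real 2.26, the highest other being 1.88.

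The first pattern is the fall of epithelial and the rise of some mesenchymal transcripts, as for Krt17 (−6.20 on the log2 scale) and Vim (3.60). GC content and gene length as the whole cause are argued against, since offsets for both left 102% of the number of called genes and 88.2% of the same genes, with medians of −4.33 for the basal and myoepithelial list and 2.08 for the transition list. A larger share of ordinary stroma that raises its cell types alike is argued against too, by limits set after the medians were seen. A larger share of fibroblasts alone was not tested. The medians of the fibroblast, endothelial, pericyte, macrophage and T and NK cell lists differed by 2.16 and lay from −2.41 to −0.25. Of the 5, 4 lay under −0.5, or 3 without lean replicate 2, obese replicate 2 or obese replicate 3. The number was also 3 with limma-voom and quality weights, where the highest median was −0.05. With offsets for GC content and gene length the highest was 0.16. The pericyte list, with the lowest median, shares 5 of 12 genes with the basal and myoepithelial list, which fell. Without the pericyte list the lowest median was −1.45 (T and NK cells). The 5 lists hold 99 genes, of which 17 are also in another list. Their most abundant genes stood at 1075 ± 62.6 against 1418 ± 1007 CPM (Sparc), 181 ± 31.1 against 53.2 ± 8.23 CPM (Eng), 61.2 ± 28.3 against 782 ± 1062 CPM (Acta2), 526 ± 139 against 805 ± 295 CPM (Lyz2) and 11.8 ± 4.75 against 44.3 ± 15.9 CPM (Lck), but they decide little: Sparc (edgeR adjusted p = 0.437, log2 change 0.19 without lean replicate 2) and Lyz2 (0.110, or 0.0222 without lean replicate 2) did not pass with all tumours, and the call of Acta2, which stood at 2335 CPM in lean replicate 2, ended without that tumour (−3.68 to −2.11, edgeR adjusted p = 0.0658) and without obese replicates 2 and 4 (0.0650 and 0.0552), over all alternatives 0.234 to 0.967, 0.0107 to 0.253 and 0.00100 to 0.0744. Another tumour cell population, a clone of the line or another line, stays open and cannot be told apart from a change of state of the same cells, because no DNA was measured: Cdkn2a stood at no more than 1.09% of the lean mean in obese replicates 1, 2 and 4 but at 14.9% in obese replicate 3, and a response of the tumour cells to the diet, the difference the design names, stays open as untested.

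The second pattern is the place of obese replicate 3 between the other obese tumours and the lean tumours. An exchange with a lean library is argued against, since on the axis from the other obese tumours (0) to the lean mean (1) it lay at 0.641, outside the lean range of 0.922 to 1.04, and no lean library lay near 0. Depth is argued against too, since its 53.8 M counts lie within the range of the other obese libraries. A mixture of lean-like and obese-like tumour cells may account for its place but cannot be told apart from a tumour in an intermediate state: it held a median of 0.347 of the lean level over 160 genes near 0 in the other obese tumours and 0.400 of the obese level over only 2 genes near 0 in the lean tumours, a sum of 0.747 where a mixture needs 0.8 to 1.2 and under 0.7 would argue against it. That answer depends on the limits for genes near 0, which had been planned at 50 CPM and 2% but were not written down with the prediction. The first run asked for 20 CPM in every library and 5% and gave 0.921 over 324 and 33 genes, and a mean of 20 CPM with 5%, run after it together with the planned limits, gave 0.922 over 453 and 43. With the planned limits, the quartiles of the share of the lean level over the 160 genes were 0.243 and 0.414. Of these genes, 81.25% had a share of 0.2 to 0.6.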

How the results depend on the processing

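Offsets for GC content and gene length, and the estimated correlation without obese replicate 3, were chosen after seeing the data. The number of changed genes stayed within 1.5 times 8819 in all 18 alternatives, from 7143 (without lean replicate 3) to 11405 (limma-voom with quality weights); leaving out 1 tumour gave 7143 to 9833. Each alternative called 79.0 to 99.6% of the same genes, with the same sign. Higher genes ran from 3820 to 4771 and lower genes from 3136 to 5107 when 1 tumour was left out. The 25 lists passed by camera became 16 with quality weights, 0 with the correlation estimated per list and 0 with it and without obese replicate 3, since their estimated correlations, all above the preset, widen the error; the cause was not tested for the quality weights. Leaving out 1 tumour gave 17 (without obese replicate 3) to 27 lists (without obese replicate 4), and 19 to 23 list scores at the smallest exact p against 28 with all tumours. With groups of unequal size, a list whose groups do not overlap need not reach the smallest exact p. Those numbers of scores are therefore not directly comparable with 28, and how much of the fall comes from this was not tested. The distance ratio of group centres was 2.30 with 500 genes and 2.01 with all tested genes. Of 2367 values for the 132 genes in the text, 2315 kept their side of the threshold, 19 lost it, 33 gained it and 0 reversed; for the lists, 772 of 899 kept it, 114 lost it, 13 gained it and 0 reversed. In simulated counts changes of 2-fold were often missed, but few genes were changed there. In the data 59.2% of tested genes passed, so the adjustment was less strict and that rate may not carry over. A gene that did not pass is still not shown to be unchanged.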

Other observations

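The genes in the next sentences were chosen after their values were seen. Igf2bp2, an RNA-binding protein gene regulated by Hmga2, stood at 165 ± 57.3 against 2.55 ± 2.79 CPM, a log2 change of 6.03 ± 0.80 (edgeR adjusted p = 0.000926), or 7.17 without lean replicate 1. The neighbouring cell cycle inhibitor genes Cdkn2a and Cdkn2b on chromosome 4 were lower, at 1.46 ± 2.54 against 35.3 ± 15.3 CPM (−4.58 ± 1.33; edgeR adjusted p = 0.0196) and 1.1 ± 1.54 against 16.4 ± 6.75 CPM (−3.85 ± 0.97; edgeR adjusted p = 0.0113). Without obese replicate 3 the change of Cdkn2a was −7.44, that of Cdkn2b −5.49 and that of Xist −3.40. In obese replicates 1 to 4 Cdkn2a stood at 0.234, 0.327, 14.9 and 1.09% of the lean mean, and Cdkn2b at 1.51, 1.11, 20.8 and 3.96%. The adjacent gene Mtap stood at 191 ± 30.5 against 154 ± 15.1 CPM (0.31 ± 0.14; edgeR adjusted p = 0.0876) and did not pass in the full set, but passed without obese replicate 2 (edgeR adjusted p = 0.0286; over all alternatives 0.0122 to 0.549). Xist, the RNA of the inactive X chromosome, stood at 135 ± 149 against 656 ± 93.8 CPM (−2.28 ± 0.68; edgeR adjusted p = 0.0223), at 5.58, 12.96, 54.5 and 9.56% of the lean mean in obese replicates 1 to 4. Its call ended without obese replicate 2 (edgeR adjusted p = 0.0584) and without obese replicate 4 (0.0564), over all alternatives 2.05e-05 to 0.0584.

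The test of the placement of genes by shuffling was chosen after the pattern was seen, and the test of GC content and gene length before its result. Over 9982 genes with a mean log2 CPM of at least 3, the median log2 change differed between chromosomes, from −0.12 on chromosome 18 to 0.59 on chromosome 10 and 0.70 on chromosome 6. The reference for these genes is not 0, since chromosome 9, with a median of 0.21, differed from the other chromosomes by only 0.00226. Differences from the other chromosomes were 0.52 (6), 0.40 (10), 0.26 (12) and 0.24 (19). On the lower side they were −0.33 (18), −0.27 (5), −0.26 (X), −0.24 (4), −0.22 (16) and −0.13 (11). Each of these had an adjusted permutation p under 0.05. Chance placement is argued against: the SD of the chromosome medians was 0.216, against at most 0.0931 in 10000 shufflings (permutation p = 0.0001, the smallest they can give), and offsets for GC content and gene length left 110.3% of it. A candidate explanation is a difference in chromosome copy number between tumour cells, as in a clone, but 10 of 20 chromosomes passed an adjusted permutation p of 0.05 and neighbouring genes can also share regulation. No DNA was measured, so copy number was not tested. The medians of chromosome 6 in obese replicates 1 to 4 were 0.61, 0.74, 0.57 and 0.85, those of chromosome 10 were 0.69, 0.64, 0.40 and 0.54, those of chromosome 12 were 0.12, 0.73, 0.31 and 0.65 and those of chromosome 18 were 0.01, −0.30, 0.10 and −0.31, so the obese tumours differed on some chromosomes.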
